A study of Mus musculus with 6 samples.

How the data were processed

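RNA of mouse bone marrow B220+ cells was sequenced in 6 libraries, 3 labelled WT and 3 labelled PELI2 knockout. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was purified with oligo(dT) beads, fragmented and reverse transcribed with random hexamers, and single-end reads of 50 bases were made on a DNBSEQ instrument. Strand use is not stated, so reads of overlapping antisense genes cannot be told apart. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the build GRCm38.p6, with no role or order.

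The values used are the FPKM per gene and library in the 1 deposited table, with no scaling across libraries stated. FPKM are not counts, so no count model was used here. The table has 27761 rows, of which 27725 have an ID in GENCODE M21 (GRCm38), and 95.7% of those have identical coordinates there, so its positions were used. No row is 0 in all 6 libraries. Rows that share a symbol (26 symbols) were told apart by ID, and 14 rows list more than 1 Entrez ID.

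Depth was worked out from the low values. For genes with 1 annotated transcript, FPKM times length is a whole number of reads once the library total is known, and the total was searched for that made most values under 6 reads whole within 0.03 reads. Between 99.3% and 99.5% of 3761 to 4164 genes came out whole. The totals were 17800000, 16600000 and 17200000 reads for WT replicates 1 to 3, and 18100000, 17000000 and 18000000 for PELI2_knockout replicates 1 to 3. At the lowest depth, 1 FPKM on a transcript of 1 kb is 16.6 reads. In simulated tables the totals found were off by at most 0.05%.

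Genes with FPKM of 1 or more in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend, two-sided, and Benjamini-Hochberg adjustment over the 12953 genes. Adjusted p under 0.05 counted as a difference. There was no replicate block. Simulated tables with 12953 genes and 3 libraries per group, made 5 times with 200 changed genes each, gave back 69.2% of genes changed by 0.5, 93.6% of those changed by 1, 96.8% of those changed by 2 and 100% of those changed by 3 (log2), and 5.8% of the calls were false. Only genes with a mean log2(FPKM + 1) above 2 were changed, and each gene varied independently with normal noise. The shares found need not hold for genes at lower FPKM or for these libraries. In those simulations, where genes vary independently, a list shifted by 0.5 was called in 5 of 5 runs by camera with the preset correlation. They give no rate of false list calls for these libraries, where genes are correlated: the 9 splits that mix the labels called 3 to 16 lists.

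Before the data were examined, 32 gene lists were fixed: the Pellino family, signalling pathways, stages of the B lineage, other cell types of marrow, and quality checks. The 30 with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01 and again with an estimated correlation. Fry tested whether the genes of a list move one way on balance, or change in either direction, without reference to other genes. Adjustment was across lists. List genes without a row were Ahsp, Siglecf, Ddx3y, Eif2s3y, Kdm5d and Uty. Lists share some members: Xbp1, Ly6c2, Cd14, Kit and Blnk are each in more than 1.

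The rule for named genes was also fixed then. It always names Peli1, Peli2 and Peli3, then in each direction up to 12 genes past the threshold with groups apart, or, with fewer than 4 of them, the 8 genes with the smallest p, leaving out predicted genes and antigen receptor segments. Up to 4 members with the smallest p may be named per list. Genes within 10 Mb of Peli2 were compared with the others by Fisher's exact test, and libraries by Pearson's r and principal components.

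Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-of-ratios scaling, rescaling to a common total of 1000000, quantile normalization, eBayes without a trend, library weights (arrayWeights), the replicate number as a block, a log2 fold change of at least 1, and each library left out. Added after seeing the data were an adjusted p under 0.1, leaving out antigen receptor segments, the granulocyte list mean as a covariate in each fitted result, and these settings for the region around Peli2 and the similarity of libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.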

Results

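The series measured messenger RNA in mouse bone marrow B220+ cells, a fraction defined by the B220 form of CD45, which B-lineage cells carry from the pro-B stage on and plasmacytoid dendritic cells carry too. There were 2 groups of 3 libraries, WT and PELI2 knockout, the latter titled CKO. Peli2 encodes a Pellino protein, an E3 ubiquitin ligase of Toll-like and interleukin-1 receptor signalling. The deposited table gives FPKM for 27761 genes, and the steps between its low values place the depth at 16600000 to 18100000 reads per library. Values are given as mean ± SD over n = 3 libraries per group, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The labels do not say that replicates are separate animals, so each p-value measures only the spread between these samples.

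Peli2 itself was not lower in the libraries labelled PELI2 knockout. Its row (ENSMUSG00000021846, GRCm38 chromosome 14, 48120823 to 48281575) stood at 2.19 ± 0.31 FPKM in WT and 2.74 ± 0.30 FPKM in the libraries labelled PELI2 knockout, and the ranges of the groups overlapped. The difference of 0.556 FPKM had p = 0.2 in a two-sided exact permutation test, in which 3 against 3 libraries cannot go below 0.1. The gene-level value does not separate exons, so a deletion that leaves most of the transcript in place would not show in it, and the row also lists the Entrez ID of Gm6498, a Gapdh pseudogene inside Peli2. Peli1, the family member with the highest FPKM, stood at 17.4 ± 0.58 FPKM in WT and 14.8 ± 0.57 FPKM in the libraries labelled PELI2 knockout, limma adjusted p = 0.153 over all genes and 0.00914 adjusted over the list alone. Peli3 lay under the expression filter, at 0.103 ± 0.0098 FPKM in WT and 0.0848 ± 0.0205 FPKM in the other group. Because the target does not separate the groups, every direction below is that of the label and not of a measured loss of Peli2.

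The comparison of the groups asks which genes differ in B220+ cells with the knockout label. Of 12953 genes tested, 3 rose and 0 fell in the libraries labelled PELI2 knockout (limma, adjusted p under 0.05). Sva (ENSMUSG00000023289, chromosome 6, 42038394 to 42042851), which encodes a secretory protein known from the seminal vesicle, was listed at 0 in each WT library and at 4.07, 4.86 and 5.44 FPKM in the libraries labelled PELI2 knockout (limma adjusted p = 0.00226). Igkv3-10 (ENSMUSG00000076596, chromosome 6, 70572633 to 70573230), a variable segment of the immunoglobulin kappa light chain, rose from 40.8 ± 2.10 to 166 ± 21.9 FPKM, a ratio of 4.08 (limma adjusted p = 0.00278). Variable segments lie outside the rule for named genes, and this one was chosen after its values were seen. Srp54 (ENSMUSG00000112449, chromosome 12, 55155104 to 55189573), a copy of the gene for a signal recognition particle subunit that targets secreted proteins to the endoplasmic reticulum, rose from 0.508 ± 0.174 to 4.47 ± 0.85 FPKM (limma adjusted p = 0.0314). It has near-identical neighbours and its value is uncertain for that reason.

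**Figure D1:**
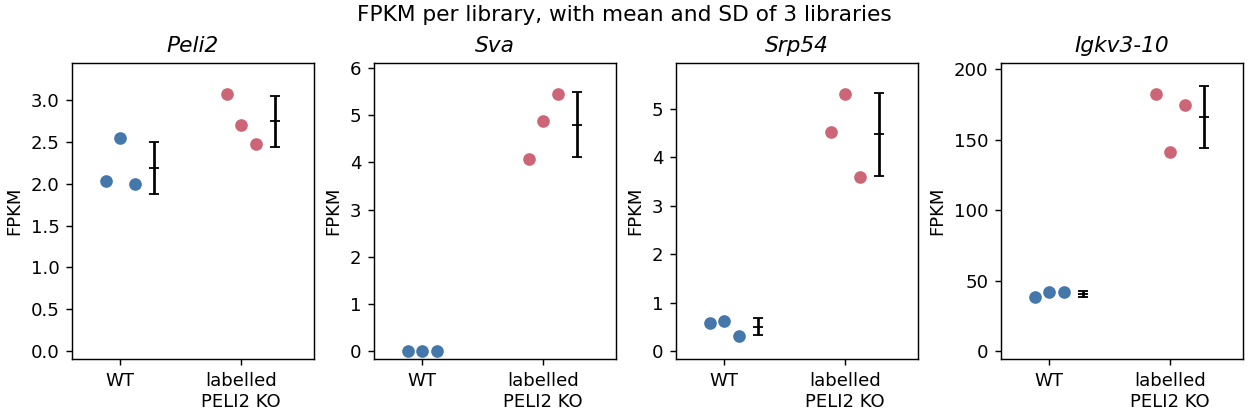
FPKM (vertical axes) of Peli2, Sva, Srp54 and Igkv3-10 in each of the 3 WT libraries and the 3 libraries labelled PELI2 knockout, with the mean and SD of each group, left out where all values are 0. Peli2 overlaps between the groups, while the other genes are higher in each library labelled PELI2 knockout than in any WT library.

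The next genes by p did not pass the threshold and are given as values. On the higher side, Ighg1, the constant region of an IgG heavy chain, stood at 32.2 ± 8.92 FPKM in WT and 155 ± 45.7 FPKM in the libraries labelled PELI2 knockout. Commd10 stood at 8.96 ± 0.86 and 19.6 ± 2.99 FPKM, and Bag3, a co-chaperone of Hsp70 proteins, at 1.93 ± 0.27 and 3.86 ± 0.24 FPKM. Gstm1, a glutathione transferase, stood at 21.2 ± 0.25 and 32.5 ± 2.74 FPKM, Khk, the kinase that opens fructose breakdown, at 14.7 ± 0.38 and 19.2 ± 0.43 FPKM, and Vat1 at 10.1 ± 0.35 and 13.7 ± 0.47 FPKM. These 6 genes share an adjusted p of 0.0908 (limma). On the lower side, Ddx58, the sensor of viral RNA called RIG-I, stood at 15.4 ± 0.62 FPKM in WT and 11.8 ± 0.25 FPKM in the libraries labelled PELI2 knockout, Parp14 at 18.9 ± 0.49 and 14.5 ± 0.23 FPKM, and Ifi214 at 2.85 ± 0.17 and 1.68 ± 0.12 FPKM. Ifi206 stood at 12.6 ± 0.92 and 8.36 ± 0.82 FPKM, Mx2 at 5.95 ± 0.29 and 4.36 ± 0.20 FPKM, and Gbp9 at 28 ± 2.39 and 20.9 ± 0.48 FPKM. Cd40, the receptor through which T cells help B cells, stood at 10.4 ± 0.02 and 8.45 ± 0.22 FPKM. The ribosomal RNA row n-R5s73 was listed at 0 in the libraries labelled PELI2 knockout and at 1.05, 1.69 and 1.63 FPKM in WT, about 2 to 3 reads per library. Adjusted p on the lower side ran from 0.0908 to 0.137 (limma).

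At an unadjusted p under 0.05 there were 2342 genes, 1192 higher and 1150 lower, where 648 would be expected by chance. The counts of list members at this threshold given below stand against this background of 2342 in 12953 tested genes. Groups did not overlap for 25.8% of the genes tested, where chance gives 10%. Sva and Igkv3-10 passed without each library in turn, while Srp54 passed only without PELI2_knockout replicate 3, where 16 genes were called. With the mean of the granulocyte list as a covariate, an alternative chosen after the values were seen, 1 gene passed and none of these 3.

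Most tested genes of the granulocyte, monocyte, erythroid and plasmacytoid dendritic cell lists were higher in the libraries labelled PELI2 knockout. Each of the 20 tested neutrophil and granulocyte genes had a higher mean there, with a median log2 fold change of 0.46. The largest log2 fold changes of the list belonged to proteins of the primary granules, at 1.37 for Mpo, 1.33 for Elane, 1.57 for Prtn3 and 1.65 for Ctsg. Mpo, myeloperoxidase, stood at 96.1 ± 22.2 FPKM in WT and 245 ± 19.5 FPKM in the libraries labelled PELI2 knockout, Elane at 126 ± 32.2 and 311 ± 28.4 FPKM, Prtn3 at 56.7 ± 13.5 and 169 ± 32.7 FPKM, and Ctsg at 33.6 ± 7.85 and 107 ± 22.5 FPKM. Each of the 20 monocyte and macrophage genes also had a higher mean, with a median of 0.36, among them Cd14 at 9.66 ± 2.78 and 18 ± 1.17 FPKM and F13a1 at 7.50 ± 1.49 and 14.4 ± 1.97 FPKM. The 17 tested erythroid genes had a median of 0.48, with Klf1, a transcription factor of red cell development, at 28.4 ± 6.39 and 44.0 ± 7.81 FPKM. Of 14 plasmacytoid dendritic cell genes 12 were higher, with a median of 0.32, and Siglech stood at 80.1 ± 10.9 and 109 ± 6.55 FPKM. The 6 tested stem and progenitor cell genes had a median of 0.32, or 0.10 with no expression filter, with Kit at 2.91 ± 0.30 and 3.90 ± 0.31 FPKM. The 21 T and NK cell genes had a median of 0.09.

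None of these members passed over all genes with all libraries (limma). Without WT replicate 1 Mpo did, with a log2 fold change of 1.16 (limma, adjusted p under 0.05). Adjusted over the list alone 14 granulocyte, 9 monocyte, 11 plasmacytoid dendritic cell, 2 stem cell, 3 T and NK cell and 0 erythroid genes passed, where 1 plasmacytoid dendritic cell gene and 1 T and NK cell gene, Cd2, were lower. At an unadjusted p under 0.05, 9 erythroid genes were higher and 0 lower. The 6 lists passed camera with its preset correlation of 0.01. With an estimated correlation none passed: the adjusted p = 0.465 for the first 5 of them (granulocyte, monocyte, erythroid, plasmacytoid dendritic cell and stem cell) and 0.702 for T and NK cells. T and NK cells also did not pass without WT replicate 1 (median 0.03), without WT replicate 2 (0.14), without PELI2_knockout replicate 3 (0.02), with library weights (0.05) or with a filter of 5 FPKM (0.13), where stem cell genes (0.32) did not pass either. The T and NK cell median was 0.18 without WT replicate 3 and 0.19 without PELI2_knockout replicate 2, where the list passed, and 0.03 when values were rescaled to a common total. Without WT replicate 1 medians were 0.30 for erythroid, 0.23 for monocyte and 0.20 for stem cell genes, and with the granulocyte covariate only plasmacytoid dendritic cell genes passed. Megakaryocyte genes (median 0.07), mast cell, basophil and eosinophil genes (median -0.04, mean -0.0047, camera upward) and stromal genes (median -0.15, mean -0.0015, camera upward) did not pass either form with all libraries. Megakaryocyte genes passed upward without PELI2_knockout replicate 1 (median 0.18), and both megakaryocyte (-0.47) and mast cell genes (-0.86) passed downward with the granulocyte covariate.

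Genes of the pro-B and pre-B stages and of B cell identity were lower in the libraries labelled PELI2 knockout. Of 26 tested pro-B and pre-B cell genes 23 were lower, with a median log2 fold change of -0.33: Lef1 stood at 7.83 ± 1.13 FPKM in WT and 5.36 ± 0.11 FPKM in the libraries labelled PELI2 knockout, Bach2, a repressor that guards B cell development, at 72.7 ± 10.4 and 52.7 ± 4.67 FPKM, and the adaptor Blnk at 52.7 ± 3.29 and 43.3 ± 2.94 FPKM. Of 22 genes of B cell identity 18 were lower, with a median of -0.34, among them the transcription factors that set the lineage: Ebf1 at 42.3 ± 4.38 and 30.8 ± 0.82 FPKM, Pax5 at 110 ± 12.2 and 84.1 ± 3.53 FPKM and Foxo1 at 28.9 ± 2.90 and 22.3 ± 1.96 FPKM. Of 25 B cell receptor signalling genes 22 were lower, with a median of -0.11, or -0.18 when values were rescaled to a common total. The 30 immature and mature B cell genes had a median of 0.01 and a mean of -0.03, and the median changed sign when values were rescaled to a common total or quantile normalized. Their list mean was not shown to move differently from that of the pro-B and pre-B genes: the later minus the earlier list differed between the groups by 0.26 (log2) with a standard error of 0.17 (two-sided exact permutation test, p = 0.3). In the same libraries the granulocyte list mean was higher by 0.62 (log2) and the erythroid list by a median of 0.48.

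No member of these lists passed over all genes (limma). Adjusted over the list alone, 13 pro-B and pre-B genes were lower and 3 higher, 13 identity genes were lower and 2 higher, 4 immature and mature genes were lower and 1 higher, and 0 receptor signalling genes passed, of which 11 were lower and 1 higher at an unadjusted p under 0.05. The lists for pro-B and pre-B cells, identity and receptor signalling passed camera with the preset correlation, and none did with an estimated correlation (adjusted p = 0.465, 0.465 and 0.470) or with the granulocyte covariate. The immature and mature list did not pass with all libraries, but passed downward without WT replicate 1 (median -0.09), without PELI2_knockout replicate 3 (median -0.08), with library weights (median -0.06), with no filter (median 0.0092) and with the granulocyte covariate (median -0.21).

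**Figure D2:**
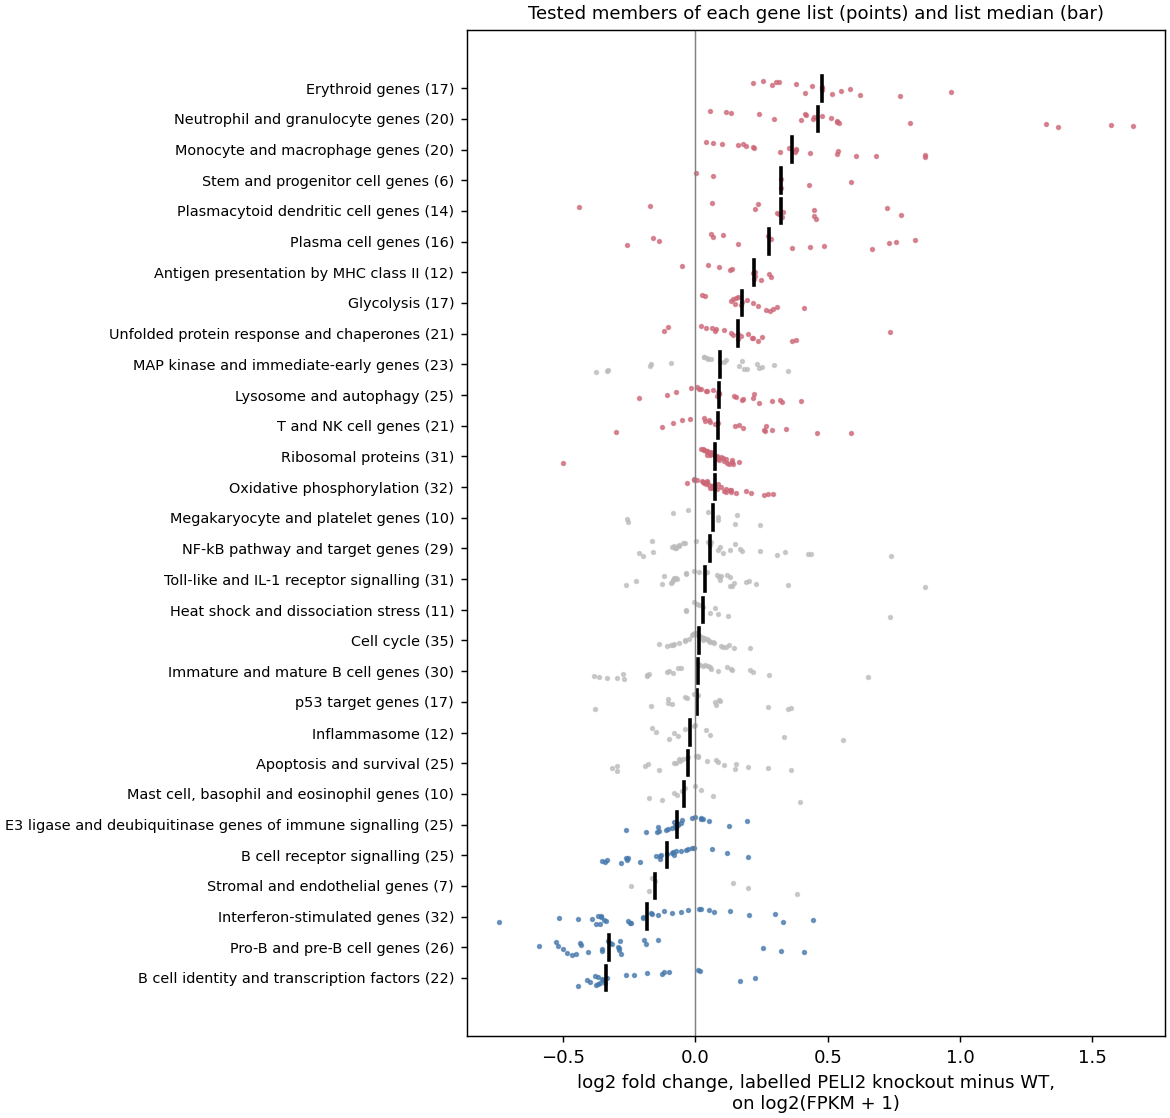
Log2 fold change on log2(FPKM + 1) (horizontal axis) of each tested member of each gene list (points, number tested in brackets) and the list median (bar), libraries labelled PELI2 knockout minus WT. Red and blue mark lists that passed camera with the preset correlation upward (13) and downward (5), grey the others, while 0 of the 30 passed with an estimated correlation. The medians run from -0.34 for B cell identity to 0.48 for erythroid genes, and those of the Toll-like receptor, NF-kB, immature B cell, cell cycle, p53 and heat shock lists change sign under at least 1 other scaling.

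Signalling lists closest to Pellino proteins did not pass with all libraries. The 31 tested Toll-like and IL-1 receptor genes had a median log2 fold change of 0.04 and the 29 NF-kB genes one of 0.05, both turning negative when values were rescaled to a common total. Within them Myd88, the adaptor of these receptors, stood at 17.5 ± 0.48 FPKM in WT and 19.3 ± 0.10 FPKM in the libraries labelled PELI2 knockout, Irak1, the kinase that Pellino proteins modify, at 22.3 ± 0.79 and 24.6 ± 0.51 FPKM, and Tnf at 7.95 ± 3.2 and 13.3 ± 0.54 FPKM. The 12 inflammasome genes had a median of -0.02 and a mean of 0.03, camera pointing upward, and Nlrp3 stood at 7.61 ± 2.68 and 9.48 ± 0.74 FPKM. The 23 MAP kinase and immediate-early genes had a median of 0.09. None of these 4 lists passed camera with all libraries, and MAP kinase and immediate-early genes passed upward without WT replicate 3 (median 0.15). Without passing, their median was 0.14 without PELI2_knockout replicate 2, 0.04 without WT replicate 1 and 0.03 without PELI2_knockout replicate 3. It was 0.02 rescaled to a common total and 0.035 with quantile normalization. Of their members 0 passed over all genes or adjusted over the list alone (limma). At an unadjusted p under 0.05 the numbers higher and lower were 4 and 0 for Toll-like receptors, 4 and 2 for NF-kB, 1 and 0 for the inflammasome, and 3 and 3 for MAP kinases. Over all 12953 tested genes they were 1192 and 1150. The 25 E3 ligase and deubiquitinase genes had a median of -0.07, or -0.15 when values were rescaled to a common total, with Traf6 at 17.5 ± 2.61 and 14.4 ± 1.30 FPKM. They passed camera downward with the preset correlation, and their adjusted p = 0.465 with an estimated correlation. They did not pass without WT replicate 2 or without PELI2_knockout replicate 3 (median -0.04 in both), with a filter of 5 FPKM (-0.07) or with the granulocyte covariate (0.0007). Of their members 0 passed over all genes (limma) or adjusted over the list alone, with 0 higher and 3 lower at an unadjusted p under 0.05.

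Interferon-stimulated genes were lower in the libraries labelled PELI2 knockout, 23 of 32 tested, with a median log2 fold change of -0.18. Besides Ddx58 and Mx2, Irf9, part of the transcription factor that acts downstream of type I interferon, stood at 26.9 ± 1.73 FPKM in WT and 22.4 ± 0.49 FPKM in the libraries labelled PELI2 knockout, and Irgm1 at 10.8 ± 0.74 and 8.98 ± 0.04 FPKM. Adjusted over the list alone 5 genes were lower and 0 higher, and 0 passed over all genes (limma), where 13 were lower and 2 higher at an unadjusted p under 0.05. The list passed camera with the preset correlation, and its adjusted p = 0.685 with an estimated correlation. It did not pass without WT replicate 3, where the median was -0.10, and the median was -0.28 when values were rescaled to a common total and -0.40 with the granulocyte covariate. The granulocyte list mean moved the other way in the same libraries, by 0.62 (log2).

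Most tested genes of glycolysis, the unfolded protein response and plasma cells were higher in the libraries labelled PELI2 knockout. Each of the 17 glycolysis genes had a higher mean, with a median log2 fold change of 0.18, among them Gpi1 at 56.7 ± 3.02 FPKM in WT and 69.1 ± 1.90 FPKM in the libraries labelled PELI2 knockout and Eno1 at 58.9 ± 3.2 and 71.0 ± 1.13 FPKM. Of 21 genes of the unfolded protein response 19 were higher, with a median of 0.16, including Xbp1, a transcription factor of secretory cells, at 55.7 ± 4.89 and 72.0 ± 5.25 FPKM, and the chaperone Calr at 172 ± 7.13 and 202 ± 4.50 FPKM. Of 16 plasma cell genes 13 were higher, with a median of 0.28, and Slpi, which granulocytes also make, stood at 37.7 ± 6.67 and 59.8 ± 0.06 FPKM. The other 3 were lower: the plasma cell markers Sdc1, at 21.8 ± 2.16 and 18 ± 1.74 FPKM, and Mzb1, at 135 ± 7.16 and 123 ± 6.65 FPKM, and Eaf2, at 2.62 ± 0.49 and 2.22 ± 0.05 FPKM. Among the higher genes, with overlapping groups, Jchain stood at 217 ± 69.4 and 353 ± 79.7 FPKM, Igha at 1146 ± 359 and 1926 ± 539 FPKM, and Ighg2b at 239 ± 128 and 390 ± 94.8 FPKM. These genes, from Sdc1 on, lie outside the rule for named genes and were chosen after their values were seen. Medians were 0.22 for 12 genes of MHC class II presentation, 0.09 for 25 lysosome genes, 0.07 for 32 genes of oxidative phosphorylation and 0.08 for 31 ribosomal protein genes. The granulocyte list mean was higher by 0.62 (log2) in the same libraries.

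Over all genes 0 members of these lists passed (limma). Adjusted over the list alone, 7 glycolysis, 8 unfolded protein response and 3 plasma cell genes were higher, and 0 genes of the other 4 lists. At an unadjusted p under 0.05 the numbers higher and lower in those 4 were 1 and 0 for MHC class II, 9 and 1 for lysosomes, 5 and 0 for oxidative phosphorylation, and 0 and 0 for ribosomal proteins. The 3 plasma cell genes that passed over the list alone were Slpi, Xbp1 and Ly6c2. None is particular to plasma cells: granulocytes also make Slpi, Xbp1 is also in the unfolded protein response list, and Ly6c2 is also in the monocyte list. The 7 lists passed camera with the preset correlation. With an estimated correlation none passed: the adjusted p = 0.465 for glycolysis, the unfolded protein response and lysosomes, 0.471 for plasma cells, 0.617 for oxidative phosphorylation, and 0.702 for MHC class II and ribosomal proteins. When values were rescaled to a common total, medians were 0.0182 for lysosomes, 0.0006 for oxidative phosphorylation, 0.15 for MHC class II, 0.09 for the unfolded protein response and 0.0021 for ribosomal proteins, which no longer passed, nor did they with quantile normalization (0.01), without WT replicate 1 (0.04) or without PELI2_knockout replicate 3 (0.02). MHC class II did not pass without WT replicate 1 (median 0.08), without PELI2_knockout replicate 3 (0.15) or with library weights (0.16), and passed downward with the granulocyte covariate (-0.35), with which of the others only the unfolded protein response passed. Without PELI2_knockout replicate 1 the plasma cell median was 0.17, and that of oxidative phosphorylation was 0.05 without WT replicate 2 or PELI2_knockout replicate 3 and 0.11 without WT replicate 3. Cell cycle (median 0.02), apoptosis (median -0.03), p53 target (median 0.01) and heat shock (median 0.03) lists did not pass with all libraries, and without PELI2_knockout replicate 1 heat shock (median 0.09) and cell cycle genes (median 0.04) passed upward.

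**Figure D3:**
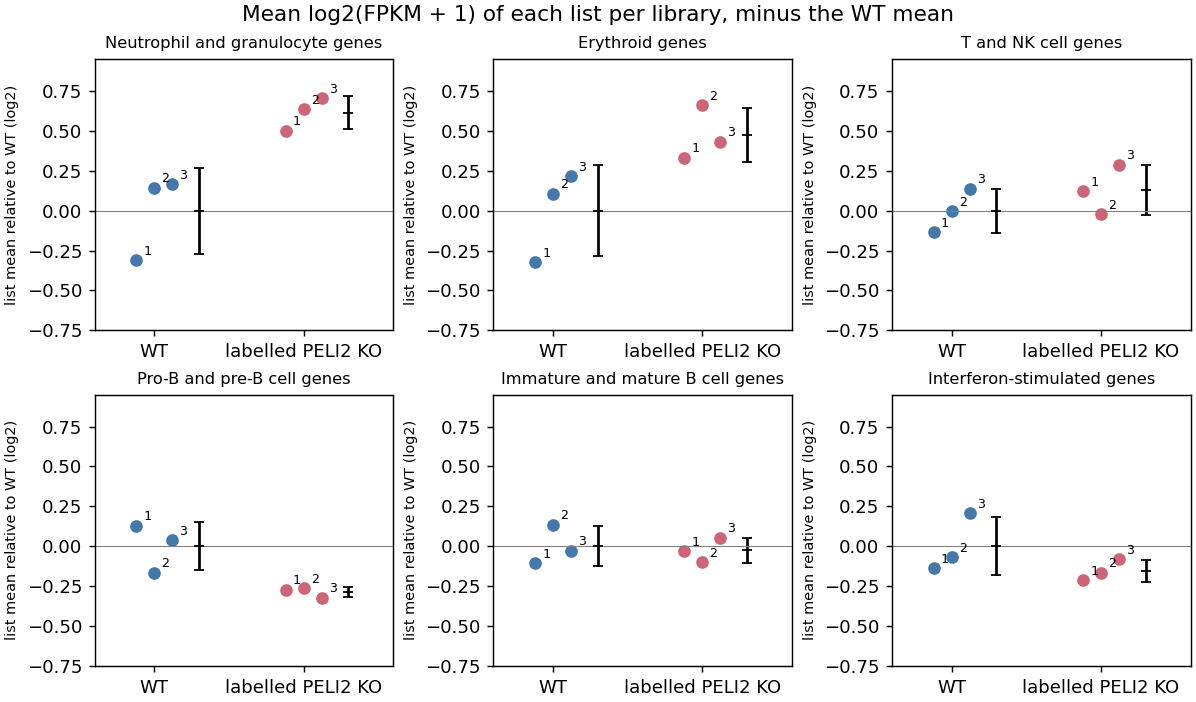
Mean log2(FPKM + 1) of 6 gene lists in each library relative to the WT mean (vertical axes), with replicate numbers, group mean and SD. The granulocyte list is higher by 0.62 in the libraries labelled PELI2 knockout and the pro-B and pre-B list lower, at -0.29, with no overlap, while T and NK cell, immature B cell and interferon lists overlap, and WT replicate 1 lies lowest for granulocyte and erythroid genes.

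In all, 18 of 30 lists passed camera with the preset correlation, 13 upward and 5 downward. With an estimated correlation 0 passed, with 1 at an unadjusted p under 0.05, and fry, which tests whether a list's genes move one way on balance, also passed 0, with 9 at an unadjusted p under 0.05. In fry's test for change in either direction 9 lists passed.

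The region around Peli2 asks whether a targeted allele brought linked differences with it. Of 146 tested genes within 10 Mb of Peli2, 17.1% had an unadjusted p under 0.05, against 18.1% of the 12807 others (Fisher's exact test, two-sided, p = 0.829), and 0 of the 146 passed the limma threshold. Fisher's exact test fell under 0.05 in opposite directions in 2 of the alternatives: the difference in percent was -6.6 without WT replicate 3 (p = 0.046) and 4.58 with the granulocyte covariate (p = 0.0291), and it was 2.9 without PELI2_knockout replicate 3 (p = 0.319), where p over the alternatives ran from 0.0291 to 1.

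Libraries of a group lay closer together on average than libraries of different groups. Pearson's r across genes, which are not independent replicates, ran from 0.984 to 0.991 within groups and from 0.976 to 0.986 between them. The first principal component held 37.6% of the variance and separated the groups, with WT replicate 1 farthest out at -23.8, against -5.58 and -6.73 for the other WT libraries and 10.6 to 13.9 for the libraries labelled PELI2 knockout. Xist was present in both groups, at 77.0 ± 1.21 FPKM in WT and 72.0 ± 3.17 FPKM in the other group, and the Y-linked genes of the list have no row in the table.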

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

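The granulocyte covariate, the adjusted p under 0.1, leaving out antigen receptor segments and all alternatives for the Peli2 region and for the similarity of libraries were chosen after the values were seen. The 3 genes called became 2 or 3 under other pseudocounts, no filter, the scalings, library weights, a fold change limit and no antigen receptor segments. They became 1 with a filter of 5 FPKM, which removes Sva and Srp54 from the test, 6 with eBayes without a trend, and 34 (27 higher and 7 lower) at an adjusted p under 0.1. Leaving out each library gave 2 to 16 genes, the 16 without PELI2_knockout replicate 3 (all higher, with 3 of 3 shared). Among the 16 were Ighg1 and the variable segments Igkv3-10, Igkv3-2, Igkv4-62, Igkv4-63, Ighv1-77 and Ighv14-2. Variable segments besides Igkv3-10 were also called without WT replicate 1 (Ighv5-9), WT replicate 2 (Igkv2-109) and WT replicate 3 (Igkv4-70). These segments lie outside the rule for named genes and were chosen after their values were seen. Peli2 kept its direction and stayed short of the threshold in all 16 settings that could be compared. The lists called ranged from 15 to 21 except for 0 with an estimated correlation, 0 with fry and 7 with the granulocyte covariate.

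Same-numbered libraries deviated from their group means with correlations of 0.101, 0.0362 and 0.0901. These are small, but each of the 6 libraries correlated best with its own number. On the second principal component both replicates 3 lay low, at -10.2 (WT) and -16.1 (PELI2_knockout), with the other libraries at positive values. Shared structure by replicate number therefore cannot be excluded. With the replicate block 4 genes were called, adding Ighg1, and 18 lists, and camera's direction turned for stromal genes (median -0.15).

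The granulocyte list mean correlates with the group at 0.88 over the 6 libraries, so this covariate takes up much of the group difference, and the median standard error of the group term goes from 0.082 to 0.153. It left 1 gene called, none of the 3, and 7 lists (2 upward and 5 downward), of which 4 were called without it. Camera's direction turned for 17 lists, for granulocyte genes by construction and otherwise with the cause not tested. MHC class II, called upward without it, was called downward with it. Medians became -0.071 for granulocyte, -0.10 for monocyte, -0.17 for erythroid, 0.0051 for stem cell, -0.16 for T and NK cell, -0.47 for megakaryocyte, -0.86 for mast cell and -1.28 for stromal genes. They became 0.0088 for pro-B and pre-B, -0.35 for MHC class II, -0.059 for Toll-like receptor, -0.062 for inflammasome, 0.0064 for MAP kinase, 0.0040 for cell cycle, 0.040 for apoptosis, -0.060 for ribosomal protein and -0.14 for heat shock genes. Single genes that changed sign with it, none past the threshold over all genes with or without it, had log2 fold changes of -0.24 (Tlr2), -0.12 (Tnf), -0.088 (Ccl4), -0.69 (Nlrp3), 0.073 (Gsdmd), 0.029 (Dusp5), 0.083 (Dusp6), 0.0083 (Tifa), -0.10 (Ctss), -0.23 (H2-DMb1), -0.14 (H2-Ab1), -0.022 (Ly6c2), -0.10 (Pmaip1) and -0.0034 (Atp5o). Others were -0.055 (Rpl3), -0.13 (Hspd1), -0.075 (Hsp90aa1), -0.23 (Hspa8), -0.086 (Il2rb), -0.13 (Car1), -0.067 (Klf1), -0.17 (Gata1), -0.081 (Epor), -0.25 (Cd9), -0.20 (Vwf), -0.34 (Gata2) and -0.25 (Ly6a). The rest were 0.031 (Cblb), 0.17 (Traf6), -0.018 (Ctsb), -0.10 (S100a8), -0.15 (S100a9), -0.31 (Hba-a1), -0.27 (Hbb-bs), 0.031 (Gfi1), 0.092 (Sdc1) and 0.22 (Eaf2). Of these genes Tifa, Ly6c2 and S100a8 had passed adjusted over the list alone without the covariate.

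Other reversals, with the cause not tested, were of lists and genes that had not passed with the main settings. Hspa8 became -0.017 rescaled to a common total and -0.031 with quantile normalization, and the cell cycle median -0.058 rescaled to a common total. With library weights Gata2 became -0.0094 and the mast cell median was -0.22. Camera or fry turned for inflammasome genes with a filter of 5 FPKM (median -0.033) and with fry (median -0.021). With 1 library left out, log2 fold changes ranged from -0.0080 to 0.10 for Hspa8, -0.50 to 0.077 for Tubb1, -0.024 to 0.18 for Vwf, -0.38 to 0.029 for Prg2, -0.54 to 0.066 for Cpa3, -0.084 to 0.20 for Gata2 and -0.79 to 0.20 for Sparc. List medians ranged from -0.028 to 0.016 for inflammasome, -0.094 to 0.079 for immature and mature B cell, -0.034 to -0.011 for apoptosis, -0.064 to 0.091 for heat shock, -0.15 to 0.18 for megakaryocyte, -0.23 to 0.20 for mast cell and -0.21 to 0.37 for stromal genes. Of these, immature and mature B cell genes passed downward without WT replicate 1 and without PELI2_knockout replicate 3, and heat shock and megakaryocyte genes upward without PELI2_knockout replicate 1, as cell cycle genes did there (median 0.045).

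The percent of genes at p under 0.05 near Peli2 minus that elsewhere became 0.1 with quantile normalization and 4.58 with the covariate, and ranged from -6.6 (without WT replicate 3) to 2.9 (without PELI2_knockout replicate 3) with 1 library left out, the cause not tested. The mean r within groups minus that between them became 0.0017 with no filter, where rows near 0 enter, and 0.0070 with a filter of 5 FPKM, where they leave. Over all settings, 2264 comparisons of single genes and 469 of single lists kept direction and side of the threshold, against 11 and 60 that lost it, 5 and 9 that gained it and 50 and 32 that turned. At 16600000 to 18100000 reads per library, genes near 1 FPKM rest on few reads, and n-R5s73 on 2 to 3 per WT library.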

Other observations

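All tests below were chosen after the result was seen, except that of early against late granulocytic genes, whose genes had not been looked at. The most abundant genes of other cell types were high in each library: S100a8 from 1829 to 3574 FPKM, S100a9 from 2764 to 4743 FPKM, Hba-a1 from 3676 to 6646 FPKM and Hbb-bs from 3772 to 7310 FPKM. These 4 genes were chosen after their values were seen. The eosinophil granule gene Prg2 stood at 1296 ± 200 FPKM in WT and 1218 ± 396 FPKM in the libraries labelled PELI2 knockout. A sort on B220 would be expected to remove most granulocytes and red cells, and no label gives the purity.

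Granulocyte, erythroid and plasmacytoid dendritic cell lists were higher and the pro-B and pre-B list lower in the libraries labelled PELI2 knockout. A lower share of B-lineage cells would raise every other cell type alike. The granulocyte list minus the T and NK cell list differed by 0.49 (log2) between the groups with a standard error of 0.13, and no library overlapped. Minus the mast cell, basophil and eosinophil list it differed by 0.62 with a standard error of 0.18. The erythroid list minus the T and NK cell list gave 0.35 with a standard error of 0.19. Each of these contrasts had p = 0.1 in a two-sided exact permutation test, the lowest that 3 against 3 libraries can give. T and NK cell genes lie lower in FPKM, where changes are understated. The list also did not move as one: adjusted over the list alone, Cd2 was lower while Nkg7 and Cd4 were higher (limma). Without Mpo, Elane, Prtn3 and Ctsg the granulocyte list mean differed by 0.40 with a standard error of 0.17. That of T and NK cells differed by 0.13 with a standard error of 0.12, and no contrast of these 2 was run. A uniform rise alone thus falls short only for the granulocyte list with those 4 genes in it. It is not excluded for the remaining granulocyte genes or the other lists. WT replicate 1 alone does not make the contrast, though it adds to it: without it the list means differed by 0.46 (log2) for granulocyte, 0.31 for erythroid, 0.27 for plasmacytoid dendritic cell and -0.22 for pro-B and pre-B genes, against 0.62, 0.48, 0.29 and -0.29 with it, and the groups stayed apart. A hypothesis from Mpo, Elane, Prtn3 and Ctsg was that early granulocytic cells gain on late ones. Their mean log2 fold change of 1.48 lay 1.08 above the 0.40 of the other granulocyte list genes. The 8 other early genes against 10 late ones did not show this gain, at 0.066 with a standard error of 0.11. Both sets were mostly higher in the libraries labelled PELI2 knockout. Of the late genes 10 were higher and 0 lower (median log2 fold change 0.33), Pglyrp1 among them. Of the early genes 7 were higher and 1 lower (median 0.36). The early genes moved unevenly in size, with Prss57 (0.72) and Cst7 (0.76) higher and Gfi1 (-0.16) lower. Their mean therefore cannot exclude such a gain. More granulocytes, early or late, red cell precursors or plasmacytoid dendritic cells in the sorted fraction, or fewer B-lineage cells, stays open, whether from the sort or from the genotype in the label.

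Sva, Srp54 and Igkv3-10 passed the threshold. Reads shared among the Srp54 copies would lower the other copies, but the other 2 changed together by -0.194 FPKM against a gain of 3.96 FPKM. A segment linked to Peli2 would place the genes on chromosome 14, and 0 of the 3 lie there. Strain segments elsewhere were not told apart from chance placement by the test run. Of the 100 genes with the smallest p, antigen receptor segments left out, 22 lie within 1 Mb of another. The mean in random sets was 15.4 (p = 0.11 in a permutation test with 10000 draws). Igkv3-10 and the other receptor segments are outside this test, so it says nothing of them. Sva and Igkv3-10 lie on the same chromosome, more than 1 Mb apart, and a longer segment holding both was not tested. A difference in strain background, or one that follows the genotype, may still lie behind the on and off pattern of Sva.

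The Peli2 row was not lower in the libraries labelled PELI2 knockout. Reads of the pseudogene Gm6498 in the row cannot be told apart from Peli2 reads: Gm6498 has a row of its own that reaches 0.175 FPKM, yet its ID is also listed with Peli2. Gapdh itself was listed at only 3.87 to 5.79 FPKM, against 66.4 ± 4.99 FPKM in WT for Pgk1 and 79.5 ± 8.01 FPKM for Aldoa. Whether reads of Gapdh and its pseudogenes are placed correctly was not tested. Exchanged group labels cannot be excluded, since the log2 fold change of Peli2, 0.23, did not pass the threshold in either direction. A conditional deletion of part of the gene, which the CKO in the titles would fit, was not tested, because the table has no exon values.

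The 6 samples can be split in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits reached the count, the real one with 3, and the highest other split gave 0. For gene lists, 1 of the 10 splits reached the count, the real one with 18, and the highest other split gave 16.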
